A study of Mus musculus with 6 samples.

How the data were processed

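Total RNA of nasal septum and rib chondrocytes was isolated with Trizol and treated with DNase, and 300 ng per sample was labelled for whole-transcript Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of processed values for the 6 arrays, and all 6 of its columns were used. The deposited values are intensities on a linear scale, and the submitters' processing notes name RMA (robust multi-array averaging) without a version. Background correction, summarisation settings and the genome build are not given in the sources used here. On each array the mean intensity after trimming 2% of the probe sets at each end was 500, as measured on the deposited values, so every array had been scaled to one level. The 25th percentiles still ran from 87.3 (rib replicate 2) to 140 (nasal replicate 1). The distributions had thus not been made equal, and which steps of RMA the deposited values went through is not known. Detection calls were not used here, so no gene could be set as above or below background, and differences of dim genes may be understated. No level of 1 gene is compared with that of another.

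The plan fixed before the data were examined took the values to be on a log2 scale. They were linear, so log2 was taken first, with no pseudocount, as the plan allowed. Of the 28451 probe sets, each identified by a RefSeq accession, 24935 matched 1 gene symbol and 0 matched several in a table of mouse RefSeq genes of assembly GRCm38.p6, which served for names only. The other 3516 had no symbol here, 2933 of them predicted transcripts. For each of the 19932 genes the probe set with the highest mean over the 6 samples was kept, which mattered for the 3236 genes with more than 1. The values of 20 genes were identical to those of another gene, among them Hbb-b2 and Hbb-bt, and cannot be assigned to 1 of them.

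Nasal minus rib differences were tested with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The fit used all 6 samples and no covariate. A positive log2 difference means higher in nasal, intensities are geometric means of the 3 samples of a group, and SE is the standard error from limma. An exact permutation test of a single gene in 3 against 3 samples cannot go below 0.1, so p-values come from limma alone. The pipeline was tested on simulated data with 19932 genes at the spread of these arrays, 200 of them changed. It recovered 8.96% of genes changed by 0.5 on the log2 scale, 83.6% at 1 and 100% at 2, with 5 false calls, and made 0 calls when no gene was changed. Far fewer genes were changed there than the 28.5% that passed in the real data. Adjustment over genes is then stricter, so these recovered shares may be too low for the real arrays.

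Gene lists, 30 in all with 704 entries, were fixed before the data were examined, and 688 entries matched a measured gene. They cover cartilage matrix, Sox and other chondrocyte transcription factors, hypertrophic chondrocytes, osteoblasts, perichondrium and fibroblasts, tendon and articular surface, skeletal muscle, erythroid cells, macrophages and osteoclasts, granulocytes, endothelium, respiratory and olfactory epithelium, glia and neurons, adipocytes, Hox genes, craniofacial patterning, somite and axial patterning, cell cycle, immediate early and heat shock genes, inflammatory and matrix-degrading genes, hypoxia and glycolysis, endoplasmic reticulum and secretion, interferon response, Hedgehog, BMP and TGF-beta, Wnt, FGF and IGF signalling, imprinted and fetal growth genes, the circadian clock and sex-linked genes. Some genes, such as Lcn2, Erg and Foxa3, are in more than 1 list. All but the sex-linked list were tested with camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 29 lists. Camera compares a list with all other genes. In the simulation it called 0 lists without a change and the 1 list that had been shifted by 0.5. The simulation drew each gene independently, with no correlation between genes and no offsets between arrays. Its counts of false calls may thus be too low for the real arrays.

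Genes were named by a rule fixed in advance. It takes the 12 largest differences in each direction among genes past the threshold with an absolute log2 difference of at least 1, no overlap between the groups and a symbol that is not a predicted, clone, small RNA, receptor or segment name. From each list it takes up to 4 members past the threshold per direction, or the 2 of highest mean where none passes. Sox9, Sox5, Sox6, Col2a1, Acan and Col10a1 were always named. A few genes that the rule takes are not reported here by name, but they are included in all counts and tests. B2m, Ddx3y and the genes named in the closing section outside this rule were chosen after their values were seen.

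Alternatives planned before the data were examined were quantile normalization, median centring, filters on dim genes at the median and the 25th percentile, eBayes with trend and robust, array weights, the mean of all probe sets of a gene, every probe set, a test against a log2 difference of 1 (treat), a test per gene without a shared prior, the replicate number as a block, and leaving out each sample in turn. For lists they also included an estimated correlation, ranks and fry. Cyclic loess was added after seeing the data. Ranges of the adjusted p of single genes leave out array weights, both filters, every probe set, treat and the test without a shared prior. Those of lists leave out array weights, the 25th percentile filter, every probe set, and trend and robust. Figures were drawn with matplotlib 3.10.9.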

Results

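Gene expression was measured with whole-transcript arrays in chondrocytes, the cells that make cartilage, taken from wild-type mice of the outbred ICR strain. The 6 samples fell into 2 groups. Nasal septum chondrocytes came from embryonic day 17.5 (n = 3) and rib chondrocytes from postnatal day 1 (n = 3). The labels name the samples of a group biological replicates. The series joins such arrays with maps of Sox9 binding and histone marks, which were not analysed here, to study how the transcription factor Sox9 controls chondrocyte genes. The arrays answer 1 question within that design, namely which transcripts differ in level between the 2 cartilages. Site and age differ together between the groups, so the values below compare nasal septum at the embryonic age with rib at the postnatal age and cannot be divided into a part due to either. Some markers of other cell types, given below, differed as well. A differing mix of cells thus cannot be told apart from a difference within chondrocytes. With 3 arrays per group, the number of arrays limits the precision of every value.

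The nasal arrays had median intensities of 261, 223 and 216 over 28451 probe sets, and the rib arrays 219, 209 and 234. Every pair of samples of a group correlated at 0.987 to 0.993 across all probe sets, against 0.957 to 0.968 for pairs that crossed the groups. Probe sets are not independent replicates, so these correlations describe the samples and test nothing. No pair held near-identical values. The first principal component held 65.2% of the variance and separated the groups. The second, with 19.6%, set nasal replicate 1 at one end.

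Among the named genes higher in the nasal samples, Hpse2, which encodes heparanase 2, had the largest difference, with 1594 in nasal and 70.5 in rib (log2 4.50, SE 0.17, limma adjusted p = 4.14e-05). Of the 12 genes at the top of this side, 3 belong to the craniofacial patterning list. Tfap2a and Tfap2b, AP-2 factors active in neural crest, stood at intensities of 912 and 684 against 84.6 and 82.4 in rib. Their log2 differences were 3.43 (SE 0.10, limma adjusted p = 2.33e-05) and 3.05 (SE 0.16). The homeobox gene Six2 was higher by 3.42 (SE 0.10).

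The other genes at the top of the nasal side were Casp4, an inflammatory caspase (3.84, SE 0.20), Eya1, which encodes a transcription cofactor (3.14, SE 0.08), the collagenase gene Mmp1a (3.17, SE 0.12), the laminin chain Lama2 (2.91, SE 0.09), the tetraspanin Tspan18 (2.89, SE 0.13), the chemokine Cxcl10 (2.84, SE 0.31), the secreted chitinase-like protein gene Chil1 (2.81, SE 0.14) and Rab27a, a GTPase of vesicle transport (2.75, SE 0.11). Cxcl10 had the widest error of the 12, with a limma adjusted p of 0.000979.

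On the rib side, 4 of the 12 genes at the top were Hox genes, which mark position along the body axis. Hoxc8 had the largest difference in either direction among the named genes, with an intensity of 3310 in rib and 111 in nasal (log2 -4.89, SE 0.18, limma adjusted p = 3.95e-05). Hoxa5 (-3.46, SE 0.11), Hoxa6 (-2.56, SE 0.17) and Hoxa7 (-2.25, SE 0.16) were also higher in rib. So were Meis1 (-3.42, SE 0.18) and Meis2 (-3.02, SE 0.11), which encode DNA-binding partners of Hox proteins. Other genes of this set were Nmu, which encodes the peptide neuromedin U (-3.83, SE 0.23), the transmembrane glycoprotein gene Gpnmb (-3.22, SE 0.09), the cytokine Il11 (-2.76, SE 0.13), Gask1b (-2.46, SE 0.16) and the annexin Anxa4 (-2.46, SE 0.08). In 16 of the 24 genes at the top of both sides, the lower group lay under the median gene intensity of 234, where background takes a larger part of the signal.

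**Figure D1:**
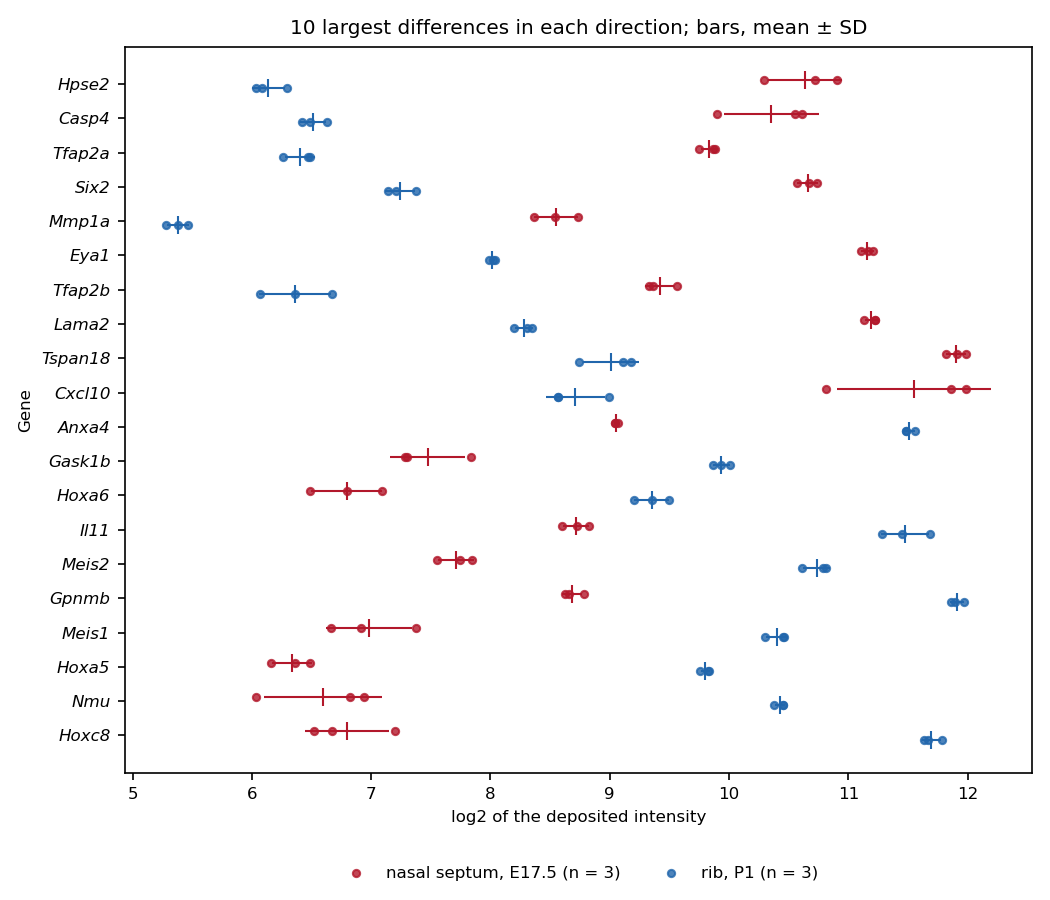
Log2 of the deposited intensity (horizontal axis) of the 10 named genes with the largest differences in each direction (vertical axis). Each dot is 1 sample, with red for nasal septum and blue for rib (n = 3 each) and bars for mean ± SD. The dots of the 2 groups do not overlap for any of the 20 genes, and Hoxc8 and Hpse2 lie at the ends with log2 differences of -4.89 and 4.50.

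Over all 19932 genes, limma placed 5683 (28.5%) past an adjusted p of 0.05, with 2746 higher in nasal and 2937 higher in rib. At least a 2-fold difference was found for 747 of them, 424 on the nasal side and 323 on the rib side. The 3 nasal and the 3 rib values did not overlap for 9099 genes (45.7%), where chance gives 10%. The median log2 difference of all genes was 0.11 towards nasal, and gene lists are therefore described relative to it. This shift lay in dim genes. The 9404 genes under the median level in both groups had a median of 0.22, while the rest had a median of -0.064. Without nasal replicate 1, whose dim genes lay highest, the dim genes had a median of 0.080 and 5764 genes passed. Leaving out rib replicate 2 gave the fewest, 3466. For each list below, the range is that of the counts adjusted over all genes, in the order of the counts, over the alternatives that tested every gene of the list, with those that left out 1 sample.

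Sox9 itself stood at 7548 in nasal and 9189 in rib, a log2 difference of -0.28 (SE 0.09, limma adjusted p = 0.0491) that lay just past the threshold. Centring each array on its median ended that call (adjusted p = 0.0678), as did the replicate block (adjusted p = 0.127) and leaving out any 1 sample. Over the alternatives that entered the ranges, the Sox9 adjusted p ran from 0.00275 to 0.146, with the value negative throughout. Its partners Sox5 (-0.14, SE 0.09, adjusted p = 0.272) and Sox6 (0.04, SE 0.12, adjusted p = 0.820) did not pass, and Sox6 changed sign under median centring (-0.02). Among the transcripts of the main cartilage matrix, Col2a1, the chain of type II collagen, had 13462 against 16032 (-0.25, SE 0.08, adjusted p = 0.0599). Acan, the aggrecan core protein, had 14440 against 12641 (0.19, SE 0.08, adjusted p = 0.126), which passed with trend and robust (adjusted p = 0.0304) and turned sign after cyclic loess (-0.03), within a range of 0.0304 to 0.811. Col2a1 and Acan lay near the top of the arrays, whose maxima ran from 17887 to 20271. Whether their differences were compressed there was not tested. Col10a1, the collagen of hypertrophic cartilage, had 4921 against 5254 (-0.09, SE 0.09, adjusted p = 0.459). Col2a1 passed as higher in rib after quantile normalization (-0.40, adjusted p = 0.00305), after cyclic loess (-0.48, adjusted p = 0.00184) and with trend and robust (adjusted p = 0.00429), within a range of 0.00184 to 0.200 over its alternatives.

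Other matrix genes differed more. Matn1, which encodes the cartilage matrix protein matrilin-1, had 11590 in nasal and 1833 in rib (log2 2.66, SE 0.09). Matn4 (1.80, SE 0.10), Otor (1.17, SE 0.08) and Edil3 (0.80, SE 0.11) were also higher in nasal. Comp, a pentameric matrix glycoprotein, was higher in rib (-1.50, SE 0.10), as was Cilp2 (-1.14, SE 0.14). Of 27 measured cartilage matrix genes, 8 were higher in nasal and 2 in rib (10 and 6 adjusted over the list alone; range 6 to 11 and 2 to 7). The list as a whole did not pass (camera adjusted p = 0.465). Its rib count depended on the scaling, with 7 rib calls after quantile normalization and after cyclic loess.

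Chondrocyte transcription factors went both ways. Arid5b, a partner of Sox9 (1.52, SE 0.09), the ETS factors Fli1 (1.26, SE 0.11) and Erg (1.25, SE 0.09) and the homeobox gene Barx2 (1.18, SE 0.09) were higher in nasal. Foxa3 (-1.40, SE 0.13), Fosl2 (-0.87, SE 0.09), Trps1 (-0.60, SE 0.09) and Sox12 (-0.57, SE 0.11) were higher in rib. Of the 34 genes in this list, 11 were higher in nasal and 8 in rib (12 and 10 adjusted over the list alone; range 7 to 14 and 5 to 11; camera adjusted p = 0.943). Median centring turned that balance, to 7 and 8.

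Genes of hypertrophic chondrocytes, the enlarged cells of mineralising cartilage, were also divided. Ibsp, a bone sialoprotein, was higher in nasal (1211 against 294, log2 2.04, SE 0.23), with Tgm2 (1.66, SE 0.09), Pdpn (0.91, SE 0.09) and Cdkn1c (0.83, SE 0.17). Spp1, which encodes osteopontin, was higher in rib (12414 against 4351, log2 -1.51, SE 0.11), with Bmp6 (-1.66, SE 0.11), Foxa3 and Ank, a pyrophosphate transporter (-1.25, SE 0.09). Of 25 genes, 5 were higher in nasal and 9 in rib (6 and 10 adjusted over the list alone; range 4 to 6 and 7 to 10; camera adjusted p = 0.129). In the osteoblast list of 17 genes, 4 were higher in nasal and 0 in rib (4 and 0 adjusted over the list alone; range 4 and 0 to 1; camera adjusted p = 0.573). They included Phex (1.13, SE 0.09), Bmp3 (0.76, SE 0.12) and Tnfsf11, which encodes RANKL (0.63, SE 0.12).

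Craniofacial patterning genes were higher in nasal as a list. Of 32 measured, 14 were higher in nasal, among them Tfap2a, Six2, Tfap2b and Pax3 (1.73, SE 0.10), and 1 in rib (17 and 1 adjusted over the list alone; range 12 to 16 and 1). The list's median lay 0.31 above that of all genes (camera adjusted p = 1.24e-05). With an estimated correlation the call was lost (adjusted p = 0.954 with an estimated correlation). The rib exception was Sim2, a transcription factor of the bHLH-PAS family, with 3145 against 713 (-2.14, SE 0.11).

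Hox genes included the largest single difference of the rib side among the named genes, that of Hoxc8, yet most members did not pass. Of 39 genes, 12 were higher in rib and 1, Hoxd1 (0.46, SE 0.13), in nasal (12 and 1 adjusted over the list alone; range 10 to 14 and 0 to 2), and Hoxd1 lost its call after quantile normalization, after cyclic loess and with trend and robust. The list's median lay 0.03 above that of all genes, while its mean of -0.47 and its test pointed to rib (camera adjusted p = 0.121). The test passed towards rib after quantile normalization (adjusted p = 0.00109), cyclic loess (adjusted p = 0.00147) and median centring (adjusted p = 0.0404) and without nasal replicate 1 or rib replicate 2. Over the alternatives that entered the ranges, its adjusted p ran up to 0.962, with an estimated correlation. In the somite and axial patterning list of 23 genes, 4 were higher in rib and 2 in nasal (4 and 2 adjusted over the list alone; range 3 to 8 and 0 to 2; camera adjusted p = 0.258). Beside Meis1 and Meis2, these were Tshz3 (-0.70, SE 0.12) and Meox2 (-0.63, SE 0.18) for rib and Mab21l1 (0.81, SE 0.18) and Mab21l2 (0.65, SE 0.17) for nasal. Meox2, Mab21l1 and Mab21l2 lost their calls in some of the fits without 1 sample, as did Hoxd1.

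**Figure D2:**
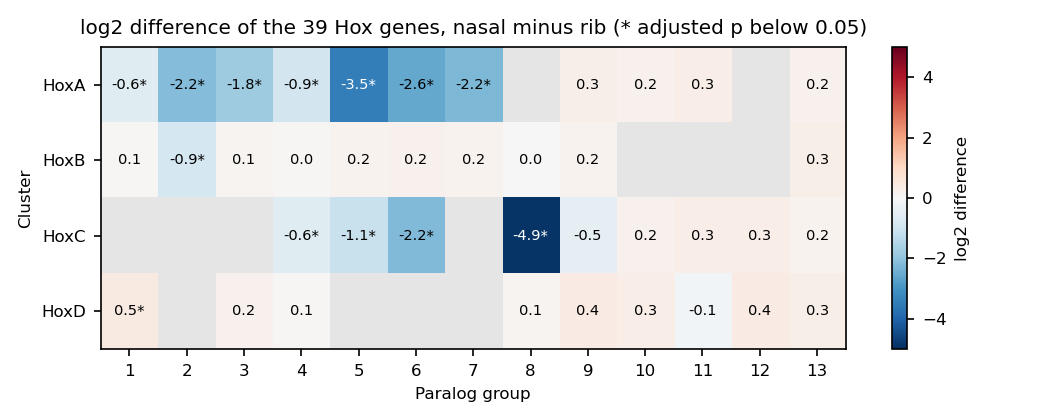
Log2 difference, nasal minus rib, of the 39 measured Hox genes by cluster (vertical axis) and paralog group (horizontal axis), blue for higher in rib and red for higher in nasal, with a star for a limma adjusted p under 0.05 and plain grey for positions with no gene in the list. The 12 genes higher in rib comprise 7 of HoxA, 4 of HoxC and 1 of HoxB, on the deposited scale.

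Interferon-response genes were higher in nasal as a list. Cxcl10 (2999 against 419), Ifit3 (2.67, SE 0.19), Gbp2 (2.25, SE 0.23) and Ifit2 (1.29, SE 0.11) led it. Of 20 genes, 12 were higher in nasal and 0 in rib (15 and 0 adjusted over the list alone; range 10 to 14 and 0). The median lay 0.57 above that of all genes (camera adjusted p = 1.12e-05; adjusted p = 0.767 with an estimated correlation). The abundant member B2m, the light chain of class I histocompatibility molecules, had 4702 against 3028 (0.64, SE 0.13).

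Inflammatory and matrix-degrading genes were the third list to pass. Ptges, a prostaglandin E synthase (2577 against 467, log2 2.46, SE 0.11), the stromelysin gene Mmp3 (2.30, SE 0.15), the adhesion molecule Icam1 (2.11, SE 0.19) and the lipocalin Lcn2 (2.03, SE 0.14) were higher in nasal. Il11 and the cyclooxygenase gene Ptgs2 (-0.81, SE 0.15) were higher in rib. Of 27 genes, 15 were higher in nasal and 2 in rib (16 and 2 adjusted over the list alone; range 12 to 17 and 2 to 3), and the median lay 0.44 above that of all genes (camera adjusted p = 0.000732; adjusted p = 0.770 with an estimated correlation). The immediate early and heat shock genes, which respond within the time of tissue handling, did not pass as a list (camera adjusted p = 0.0622). They did after quantile normalization (adjusted p = 0.00367) and cyclic loess (adjusted p = 0.00722), on ranks and without nasal replicate 1 or rib replicate 1 or 2. The highest adjusted p over the alternatives that entered the ranges was 0.962, with an estimated correlation. Of their 25 genes, 11 were higher in nasal, led by Hspa1a (1.35, SE 0.22), Hsph1 (1.27, SE 0.13), Zfp36 (1.05, SE 0.16) and Atf3 (0.93, SE 0.13), and 3 in rib, namely Egr3 (-0.78, SE 0.08), Dusp1 (-0.41, SE 0.10) and Nr4a1 (-0.33, SE 0.10). Adjusted over the list alone, the counts were 15 and 5 (range 9 to 15 and 1 to 6). Nr4a1 lost its call under median centring, and both Nr4a1 and Dusp1 lost it in fits without 1 sample.

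**Figure D3:**
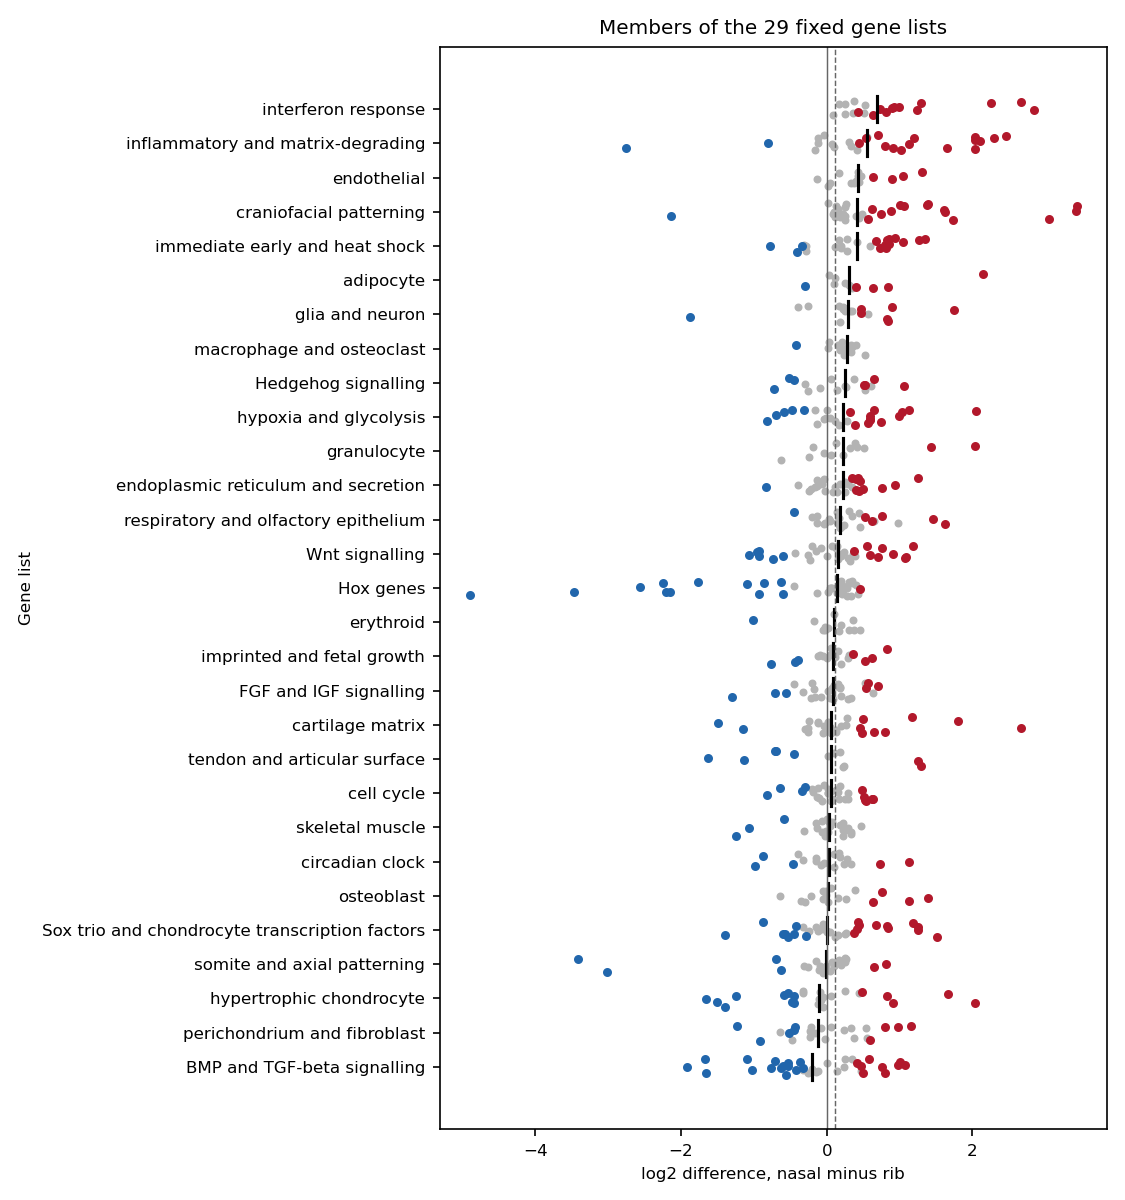
Log2 difference, nasal minus rib (horizontal axis), of every measured member of the 29 tested gene lists (vertical axis), with red for higher in nasal and blue for higher in rib at a limma adjusted p under 0.05, grey for the rest and a black bar for each list's median; the dashed line marks the median of all genes, 0.11. The interferon list has the highest median and 12 red dots, and the BMP and TGF-beta list, with 15 blue dots, the lowest.

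Growth factor pathways differed by member. In the BMP and TGF-beta list, the ligands Bmp4 (500 against 1590, log2 -1.67, SE 0.10) and Bmp6, the BMP antagonist Grem1 (-1.92, SE 0.13) and Ltbp2 (-1.10, SE 0.16) were higher in rib. The antagonists Chrdl2 (1.07, SE 0.12), Chrdl1 (0.97, SE 0.10) and Fst (0.79, SE 0.14) and the BMP modulator Bmper (1.00, SE 0.13) were higher in nasal. Of 35 genes, 15 were higher in rib and 9 in nasal (17 and 12 adjusted over the list alone; range 10 to 17 and 7 to 12; camera adjusted p = 0.127), and the list passed towards rib without nasal replicate 3. In the Wnt list of 33 genes, 9 were higher in nasal and 6 in rib (9 and 8 adjusted over the list alone; range 6 to 10 and 6 to 8; camera adjusted p = 0.922). Sfrp1 (1.18, SE 0.09), Wnt4 (1.08, SE 0.13), Dkk3 (1.07, SE 0.16) and Wnt5a (0.91, SE 0.11) were on the nasal side and Lef1 (-1.07, SE 0.12), Fzd2 (-0.96, SE 0.10), Sfrp4 (-0.93, SE 0.11) and Wif1 (-0.92, SE 0.10) on the rib side.

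Hedgehog genes went both ways. Ptch1, a receptor that the pathway itself induces (0.51, SE 0.12), Foxf1 (1.06, SE 0.10), Gas1 (0.65, SE 0.13) and Pthlh (0.52, SE 0.14) were higher in nasal, and the ligand Ihh (-0.45, SE 0.11), Gli3 (-0.73, SE 0.10) and Boc (-0.51, SE 0.14) in rib. These made 4 and 3 of 17 genes (8 and 4 adjusted over the list alone; range 2 to 8 and 1 to 5; camera adjusted p = 0.735), but Ptch1, Pthlh, Ihh and Boc each lost the call in 4 or 5 of the 6 fits without 1 sample. In the FGF and IGF list, 3 of 28 genes were higher in nasal and 3 in rib (3 and 3 adjusted over the list alone; range 3 to 5 and 2 to 7; camera adjusted p = 0.954). Fgf2 (0.70, SE 0.08), Igf1r (0.56, SE 0.08) and Dusp6 (0.53, SE 0.09) stood against the insulin receptor substrate Irs1 (-1.30, SE 0.13), Etv5 (-0.70, SE 0.14) and Spry2 (-0.56, SE 0.13), the last of which lost its call in 3 fits without 1 sample. That list's median of 0.08 was positive, but lay 0.03 under that of all genes, and its test pointed to rib.

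Hypoxia, glycolysis and secretory genes had more members higher in nasal than in rib but did not pass camera as deposited. Among 26 hypoxia and glycolysis genes, 12 were higher in nasal and 5 in rib (12 and 5 adjusted over the list alone; range 8 to 12 and 2 to 6; camera adjusted p = 0.209). The carbonic anhydrase Car12 (2.04, SE 0.10), Egln3 (1.13, SE 0.11), Bnip3 (1.03, SE 0.14) and Pgk1 (0.99, SE 0.22) were on the nasal side. Vegfa, at 6059 in rib and 4046 in nasal (-0.58, SE 0.10), Ero1a (-0.81, SE 0.10), Adm (-0.70, SE 0.16) and Pfkfb3 (-0.47, SE 0.10) were on the rib side. Pgk1, Adm and Pfkfb3 were not called in some fits without 1 sample. Among 31 genes of the endoplasmic reticulum and secretion, 10 were higher in nasal and 1 in rib (13 and 2 adjusted over the list alone; range 5 to 15 and 1 to 3; camera adjusted p = 0.172), and the test passed towards nasal without nasal replicate 1 (adjusted p = 0.0232), within a range of 0.0232 to 0.962. Manf (1.25, SE 0.15), Sdf2l1 (0.94, SE 0.16), Pdia4 (0.75, SE 0.09) and the collagen chaperone Serpinh1 (0.49, SE 0.08) stood against the collagen prolyl hydroxylase P3h2 (-0.84, SE 0.11). Of 30 cell cycle genes, 6 were higher in nasal and 4 in rib (6 and 4 adjusted over the list alone; range 5 to 11 and 2 to 4; camera adjusted p = 0.820), and 11 and 2 after cyclic loess. Ccnb2 (0.63, SE 0.09), Rrm2 (0.61, SE 0.08), Top2a (0.55, SE 0.09) and Tyms (0.52, SE 0.16) were higher in nasal and Plk1 (-0.83, SE 0.10), Kif20a (-0.65, SE 0.10), Mcm7 (-0.34, SE 0.09) and Mcm2 (-0.30, SE 0.08) in rib. Tyms lost its call under median centring and with the mean of probe sets, Mcm7 after cyclic loess and Mcm2 after cyclic loess and quantile normalization, and all 3 in 5 of the 6 fits without 1 sample.

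Markers of the connective tissues around cartilage were present on both sides. In the perichondrium and fibroblast list of 24 genes, 4 were higher in nasal, led by the microfibril gene Fbn1 (1.16, SE 0.10) and elastin, Eln (0.98, SE 0.10), and 5 in rib, led by Igfbp6 (-1.23, SE 0.15) and Col14a1 (-0.92, SE 0.20). The counts adjusted over the list alone were 4 and 5 (range 3 to 7 and 2 to 7; camera adjusted p = 0.735), and 7 and 7 passed after quantile normalization. Col14a1 was not called without nasal replicate 2 or rib replicate 2. In the tendon and articular surface list of 12 genes, 2 were higher in nasal, Abi3bp (1.29, SE 0.26) and Erg, and 5 in rib, including Tnmd (-1.63, SE 0.32), Thbs4 (-1.14, SE 0.31), Gdf5 (-0.71, SE 0.12) and Clu (-0.69, SE 0.10). Thbs4 lost its call with trend and robust and in 5 fits without 1 sample. Adjusted over the list alone the counts were also 2 and 5 (range 1 to 2 and 3 to 5). The median of this list was 0.06, while its mean of -0.11 and its test pointed to rib (camera adjusted p = 0.600). Of 25 skeletal muscle genes, 3 were higher in rib and 0 in nasal (1 and 0 adjusted over the list alone; range 1 to 5 and 0 to 2). They were Tnnt3 (-1.24, SE 0.13), Myl1 (-1.07, SE 0.29) and Acta1 (-0.58, SE 0.15), and 5 passed towards rib after cyclic loess, while Myl1 and Acta1 each lost the call in 4 fits without 1 sample. The muscle median of 0.03 and mean of -0.03 differed in sign, and the test pointed to rib (camera adjusted p = 0.820).

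Markers of blood, vessel, epithelial, nerve and fat cells were mostly dim. The medians of these lists lay at intensities of 94.0 to 184, under the median gene, and thus within the range where nasal replicate 1 lay higher than the other arrays. Of 15 endothelial genes, 4 were higher in nasal, namely Emcn (1.30, SE 0.19), Cdh5 (1.05, SE 0.22), Eng (0.90, SE 0.09) and Vwf (0.63, SE 0.12), and 0 in rib (4 and 0 adjusted over the list alone; range 3 to 6 and 0). The endothelial list missed the threshold (camera adjusted p = 0.0534). It passed after quantile normalization (adjusted p = 0.0228) and cyclic loess (adjusted p = 0.0183), under median centring, on ranks and in 5 fits without 1 sample. Its range was 0.0108 to 0.962 over the alternatives that entered the ranges. Of 20 macrophage and osteoclast genes, 0 were higher in nasal and 1, the osteoclast protease Ctsk (-0.42, SE 0.13), in rib (0 and 0 adjusted over the list alone; range 0 to 3 and 0 to 1; camera adjusted p = 0.209). After cyclic loess this count was 3 and 0, and Ctsk lost its call there, after quantile normalization and in 5 fits without 1 sample. Of 13 granulocyte genes, Lcn2 and Ltf (1.43, SE 0.41) were higher in nasal and 0 in rib (1 and 0 adjusted over the list alone; range 1 to 2 and 0 to 3; camera adjusted p = 0.573), against 2 and 3 after cyclic loess. Ltf lost its call with trend and robust and in 4 fits without 1 sample. Of 13 erythroid genes, 0 were higher in nasal and 1, Alas2 (-1.02, SE 0.21), in rib (0 and 1 adjusted over the list alone; range 0 and 0 to 2; camera adjusted p = 0.939).

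In the respiratory and olfactory epithelium list of 26 genes, 5 were higher in nasal and 1 in rib (5 and 1 adjusted over the list alone; range 2 to 9 and 1 to 2; camera adjusted p = 0.135). Reg3g (1.63, SE 0.20), Cyp2f2 (1.46, SE 0.30), the olfactory marker protein gene Omp (0.76, SE 0.16) and Scgb1c1 (0.62, SE 0.16) were on the nasal side, and Epcam (-0.45, SE 0.09) on the rib side. Omp lost its call without rib replicate 1 and Scgb1c1 in 4 fits without 1 sample, while the list passed without nasal replicate 2 (adjusted p = 0.0430), within a range of 0.0430 to 0.962. Of 18 glia and neuron genes, 6 were higher in nasal and 1 in rib (8 and 2 adjusted over the list alone; range 3 to 7 and 1 to 3; camera adjusted p = 0.135). The Schwann cell genes Erbb3 (1.74, SE 0.11) and Sox10 (0.85, SE 0.11) and the neuronal genes Nefl (0.89, SE 0.17) and Stmn2 (0.83, SE 0.23) stood against Fabp7, at 5107 in rib and 1389 in nasal (-1.88, SE 0.14), and Stmn2 was not called in 4 fits without 1 sample. Of 12 adipocyte genes, 4 were higher in nasal and 1 in rib (4 and 1 adjusted over the list alone; range 2 to 5 and 0 to 1; camera adjusted p = 0.135). The fatty acid carrier Fabp4 (2.14, SE 0.15), Lpl (0.84, SE 0.11), Ucp1 (0.63, SE 0.14) and Cidea (0.40, SE 0.08) were higher in nasal and Pparg (-0.30, SE 0.09) in rib; Cidea and Pparg lost their calls after quantile normalization, median centring and cyclic loess, and Pparg with the mean of probe sets. Leaving out rib replicate 1 ended the calls of Ucp1 and Cidea, and leaving out any 1 sample that of Pparg.

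Of 18 imprinted and fetal growth genes, 4 were higher in nasal and 3 in rib (4 and 3 adjusted over the list alone; range 2 to 6 and 2 to 5; camera adjusted p = 0.844), and 4 and 5 after cyclic loess. Cdkn1c, Sgce (0.62, SE 0.10), Igf2bp1 (0.53, SE 0.12) and Igf2bp2 (0.36, SE 0.09) stood against Hmga2 (-0.76, SE 0.10), Igf2bp3 (-0.44, SE 0.09) and Peg10 (-0.39, SE 0.10). Igf2bp2 lost its call under median centring, and Igf2bp1, Igf2bp2 and Peg10 lost it in 3 or 4 fits without 1 sample. Of 18 circadian clock genes, 2 were higher in nasal, Nfil3 (1.13, SE 0.09) and Hlf (0.74, SE 0.15), and 3 in rib, including Ciart (-0.88, SE 0.10) and Per1 (-0.46, SE 0.11), a balance that turned to 6 and 4 after cyclic loess. Per1 was not called in 3 fits without 1 sample. Adjusted over the list alone, the counts were 2 and 3 (range 1 to 6 and 2 to 5). The clock median of 0.03 and mean of -0.01 differed in sign, and the test pointed to rib (camera adjusted p = 0.735). Among the 5 sex-linked genes, Xist, which is expressed from the inactive X chromosome of females, was higher in nasal (6970 against 3515, log2 0.99, SE 0.24, limma adjusted p = 0.0214). The Y-linked gene Eif2s3y was higher in rib (-0.74, SE 0.23, limma adjusted p = 0.0486), and lost its call after quantile normalization (adjusted p = 0.0540), cyclic loess (adjusted p = 0.0622) and trend and robust (adjusted p = 0.103) and in 4 fits without 1 sample, within a range of 0.00648 to 0.125 over its alternatives. The call of Xist was lost with trend and robust (adjusted p = 0.0663) and without nasal replicate 2 or 3 or rib replicate 2 or 3, within a range of 0.00402 to 0.0718. Adjusted over the list alone, 1 was higher in nasal and 1 in rib (range 0 to 1 and 0 to 1). Xist ranged from 2962 to 9078 over the 6 samples and the Y-linked Ddx3y from 1028 to 1704, and nasal replicate 3 had the highest Xist value and the lowest Ddx3y value. Xist and Ddx3y lay above the median gene intensity of 234 in every sample, so each sample appears to hold RNA of both sexes. The spread among replicates would then be between pools of animals. The share of each sex is not known, and the Xist and Eif2s3y differences may reflect it.

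Of the 29 lists tested, 3 passed camera with the preset correlation and 0 with an estimated one. Fry, which tests each list by itself for change in either direction, passed 27. By direction fry passed 10, which were these 3, cartilage matrix, chondrocyte transcription factors, osteoblast, hypoxia and secretion towards nasal, and hypertrophic and BMP genes towards rib. In 6 lists the median lay below that of all genes while the test pointed to nasal, namely cartilage matrix (-0.051), chondrocyte transcription factors (-0.11), osteoblast (-0.098), erythroid (-0.011), cell cycle (-0.060) and imprinted and fetal growth genes (-0.028), and each of these 6 tests missed the threshold.

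**Figure D4:**
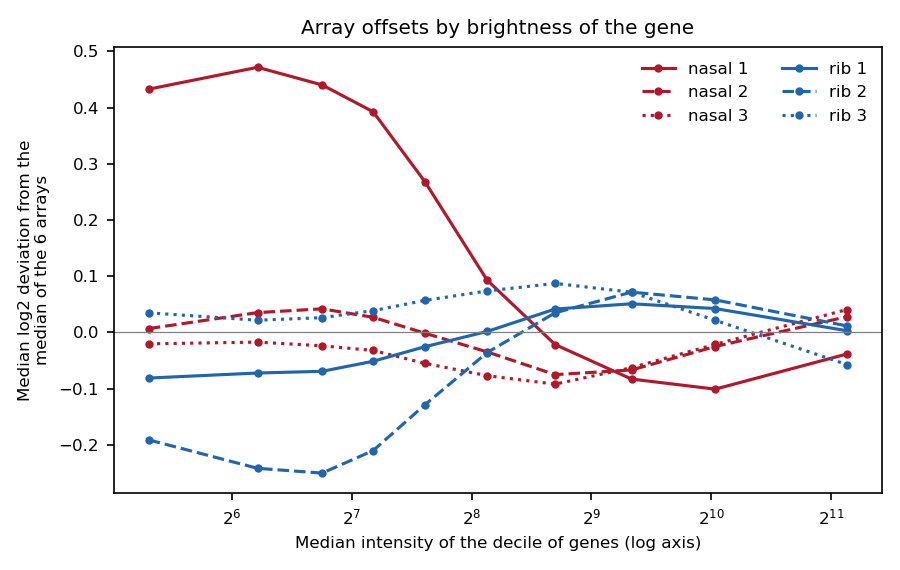
Median log2 deviation of each array from the median of the 6 arrays (vertical axis) over 10 equal bins of genes by brightness, plotted at the median intensity of each bin on a log axis, with red for nasal, blue for rib and line styles for replicates 1 to 3. In the dimmest bin nasal replicate 1 lies 0.43 above the median of the arrays and rib replicate 2 lies at -0.19, and in the brightest bin these values are -0.04 and 0.01.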

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

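All alternatives but cyclic loess were planned. Apart from treat, the number of genes past the threshold stayed within 1.5 times 5683 under each alternative that kept all 6 samples, from 3903 to 8516, and 0 of the 5683 genes were called in the opposite direction under those that tested the same genes. Leaving out 1 sample gave 3466 (without rib replicate 2) to 5764 (without nasal replicate 1), with 1639 to 2596 higher in nasal and 1827 to 3168 higher in rib. The rib count without nasal replicate 2 was 1953. Array weights raised the nasal count to 4344. Of the 747 genes with at least a 2-fold difference, the treat test against that size kept 124. Such a test asks more than a threshold on the estimate. Quantile normalization gave 6884 genes, median centring 6062, cyclic loess 6968, genes above the median level 6211 of 10528 and trend with robust 6878. Nasal shares were 48.3% as deposited and 41.7% among genes above the median level. The tests per gene without a shared prior gave 4756.

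The 3 lists past the threshold became 6 after quantile normalization, after cyclic loess and among genes above the median level, with 5 higher in nasal and 1 in rib each time. That filter keeps a gene by its level in either group, which left 9 of 39 Hox and 17 of 32 craniofacial genes, so its list results partly reflect the selection. Median centring gave 5, with 1 in rib. Ranks gave 5, all higher in nasal. An estimated correlation gave 0, and 0 in nasal. Fry gave 10 by direction, 8 in nasal and 2 in rib, and 27 for change in either direction. Leaving out 1 sample gave 4 to 7 lists, 4 to 6 in nasal and 0 to 1 in rib. Nasal replicate 1 left out gave the 7. The causes were not tested. The craniofacial, interferon and inflammatory lists passed in each of these leave-one-out fits.

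The labels do not say that the replicate numbers pair the samples. Same-numbered deviations from the group means correlated at -0.02, 0.22 and -0.28, and not every sample correlated best with its own number. With 3 samples per group and brightness offsets between the arrays, these correlations cannot decide whether a pairing exists. With the replicate block 3903 genes passed, 1939 of them higher in nasal. The highest correlation across groups was 0.904 in genes above the median level, against 0.968 over all probe sets. That filter narrows the range of intensities, which can lower a correlation by itself. All 24 leading genes passed under each setting that entered the ranges of single genes. Of the 177 named genes, 7 lost and 1 gained a call after cyclic loess, 6 and 1 after quantile normalization, 6 and 0 after median centring, 5 and 2 with trend and robust, 2 and 0 with the mean of probe sets and 25 and 0 with the replicate block. Without nasal replicate 1, 2 or 3, 9, 27 and 19 lost it, and without rib replicate 1, 2 or 3, 32, 33 and 24, in all 38 different genes. Signal over background could not be set without detection calls, which limits what can be said of dim genes.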

Other observations

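The tests on the immune genes and the dim genes were chosen after the values were seen, as were cyclic loess and the grouping of Hox genes by cluster; the other tests were set before their results. Among 615 gene families defined by a shared symbol stem, 21 passed camera on the deposited values, 5 after cyclic loess and 4 on both, with 0 at an estimated correlation (adjusted p = 0.988). The counts and medians of families given here are those of the deposited values. The vacuolar protein sorting genes (Vps, 34 measured) passed as lower in nasal on both scales, with 19 higher in rib and 3 in nasal and a median of -0.36. Small nucleolar RNA genes of the Snora class (24 measured) had 10 higher in nasal and 0 in rib, with a median of 0.45. Adamts genes, a family of matrix-cleaving proteases (19 measured), had 7 higher in nasal and 0 in rib, with a median of 0.33. Several Adamts genes were dim, and dim genes as a set had a median of 0.22 on that scale. The Hoxa genes made the fourth family. Mitochondrial ribosomal protein genes (Mrpl, 48 measured) had 19 higher in rib and 2 in nasal as deposited, with a median of -0.26, but the family missed the threshold after cyclic loess (adjusted p = 0.0949).

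Of the 3516 probe sets with no symbol here, 585 passed the threshold, 361 of them higher in nasal and 224 in rib. With 10 splits of the 6 samples into 3 and 3 no share under 0.05 can be reached. The real split gave 5683 genes, as the 1 split with as many, and the highest of the other splits gave 0. For lists, 9 of the 10 splits gave as many as the real one, which gave 3 while the highest other gave 15. The cause of these list counts was not tested. After cyclic loess the real split gave 6 lists and the others 0 to 6, with 2 of the 10 splits at 6. The mean shift of the craniofacial list was 0.67 in the real split and at most 0.27 in the others, that of the interferon list 0.83 and 0.41, and that of the inflammatory list 0.63 and 0.38. Each other split mixes the groups, so it keeps only a part of the real difference and holds the rest as spread. Smaller shifts and fewer genes there were thus fixed by design, and these splits test neither.

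The interferon-response list was higher in nasal with the preset correlation (adjusted p = 0.767 with an estimated correlation). A brightness-dependent offset between the arrays is argued against as the whole source, since the median nasal minus rib offset was at most 0.27 in any brightness bin. The mean difference of the list relative to all genes was 0.83 as deposited and 0.79 after cyclic loess. With so small an offset, cyclic loess could not have removed most of that difference, so its result adds little. A single nasal sample is argued against as well, since the lowest mean difference with 1 nasal sample left out was 0.79. More immune cells in the nasal samples stay open, since 8 macrophage and leukocyte genes (Lyz2, Ctss, C1qa, C1qb, C1qc, Tyrobp, Fcer1g and Ptprc) had a median of -0.014 after cyclic loess but all lay under the median gene level, with Lyz2 at 98.2 and 88.6, which decides nothing. A response of the nasal chondrocytes to interferon at this site or age may also be the source, and site, age and cell isolation were not tested apart.

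Dim genes were higher in nasal on the deposited scale, with 849 called in nasal and 160 in rib among 9404. Leaving out nasal replicate 1 took their median difference from 0.22 to 0.080, with 651 and 347 called, which is consistent with a raised low end on that array; without rib replicate 2, whose dim genes lay lowest, the median was 0.15, with 371 and 80 called. After cyclic loess the counts were 738 and 772. The median intensity of the dim genes was 136, 105 and 98.7 on nasal replicates 1 to 3 and 94.7, 84.2 and 103 on rib replicates 1 to 3. The arrays of the 2 groups thus overlapped, and a general rise of dim genes was not seen on every nasal array. Real expression of single dim genes in nasal stays open. Olfactory and vomeronasal receptor genes (1256) had a median difference of 0.24 against 0.22 for the other dim genes, which decides nothing, since epithelium carried over with the nasal septum could raise them too and 5 genes of the epithelium list were higher in nasal.

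Hox genes higher in rib lay mainly in the HoxA and HoxC clusters. In paralog groups 1 to 8, all 11 HoxA and HoxC genes were higher in rib, against 1 of 12 HoxB and HoxD genes, Hoxb2, as deposited and after cyclic loess. This division was drawn from the calls themselves, so it was not tested. In groups 9 and above 0 of 16 were higher in rib as deposited and 2, Hoxc9 and Hoxd11, after cyclic loess. A brightness-dependent offset hiding HoxB and HoxD genes was examined with cyclic loess, after which 1 of those 12 was called, Hoxb2 as before. The median nasal minus rib offset was at most 0.27 in any brightness bin. At most small differences could thus have been hidden, and the count does not decide on those. Site, age and probe sets that respond poorly in HoxB and HoxD stay open, as untested.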
